A study of Homo sapiens with 10 samples.

How the data were processed

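Poly(A) RNA of 10 libraries from 2 multiple myeloma cell lines, H929 and OCI, was sequenced as paired ends on a NovaSeq instrument, per the labels' protocols. The labels do not say which OCI line was used. The authors deposited 1 table of FPKM values, fragments scaled by transcript length and by library total, for 58229 genes. HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 are named per the submitters' processing notes, without their roles. The same notes name the mouse build mm8, whereas the gene identifiers are human Ensembl identifiers, so the build is unclear and no coordinates are given. The extract protocol in the labels also speaks of adipose material. How reads that match several places were assigned, and whether strand was used, is not given in the sources used here. Values of near-identical gene copies and of antisense genes are therefore uncertain. All 10 columns were mapped to libraries by their names; those of the wild-type libraries carry a suffix, ZY, that the labels do not explain.

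No read counts were used here, so no counting intervals or floors are given, and a value of 0 may be a failed estimate and is described only as listed at 0. Relative depth was read from the steps between values of genes with a mean under 0.1 FPKM, as the commonest ratio to the OCI wild-type library. In all 45 pairs of libraries, the pair's own commonest ratio matched the one implied by these ratios within 0.025 log2. Gene names were taken from a table of gene identifiers, which matched 57518 identifiers, 41822 of them with a symbol. Of the tested genes 12041 had a symbol, 10881 were protein-coding in GENCODE 29 and 628 were listed at 0 in some library.

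FPKM values were analysed as log2(FPKM + 1) for the 12872 genes with a mean of at least 1 FPKM, with limma 3.58.1 in R 4.3.3. An additive model of cell line and manipulation was fitted to all 10 libraries (5 residual degrees of freedom) with moderated variances that follow a trend with expression, and two-sided p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Whether a manipulation acted differently in the lines was tested in a model of 8 group means (2 residual degrees of freedom), whose spread comes from the knockdown pairs alone. Of 30 gene lists written before the data were examined, 801 of 803 entries were found, and 26 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The calls of camera were lost in all 5 comparisons with an estimated correlation.

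Named genes were chosen by a rule written before the data were examined. It takes AIMP1; in each direction up to 10 genes with a symbol and the same sign in every library of the comparison, first those past the threshold by size of change, then those whose smallest change was largest; up to 4 members with the largest change and the same sign in every library from each list that camera called or that held a called gene; and up to 5 called genes per direction of each comparison by line. Some genes that the rule names are not reported here.

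The procedure was tested on simulated data, with 50 genes changed at each log2 size of 1, 2, 3 and 4 in 12872 genes. The Benjamini-Hochberg adjustment is stricter where fewer genes change strongly. The recovery given here therefore does not hold for data with few changed genes. At a change of 2, 90.0% of the genes were recovered for knockdown, 76.0% for overexpression, 66.0% for protein, 94.0% for knockdown against overexpression and 98.0% for OCI against H929. The comparisons by line recovered 10.0%, 0% and 0% at that size, and made 10 false calls for knockdown, 4 for overexpression and 2 for protein, above the nominal rate. The 5 other comparisons made 9, 5, 6, 13 and 13 false calls in that order. camera recovered 5, 5, 4, 5 and 5 of 5 raised lists, with 1 false list for knockdown. Simulated genes varied independently of each other, whereas the estimated correlation in the data was 0.837 within heat shock genes and 0.716 within ribosomal proteins. The count of false lists therefore does not gauge camera where members of a list vary together. Alternatives were another pseudocount, other filters, median centring, quantile normalization, other moderation, no term for the line, group means, a replicate block, and leaving out each library. Correlations between comparisons that share wild-type libraries are given beside the mean of 100 simulations with no change.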

Results

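The series measured mRNA in 10 libraries of multiple myeloma cells from 2 lines, H929 and a line labelled OCI. In each line, wild-type cells, cells overexpressing AIMP1 and cells treated with AIMP1 protein gave 1 library each, and cells with AIMP1 knockdown gave 2. AIMP1 is a scaffold protein of the multi-tRNA synthetase complex that is also secreted. The comparisons asked how each manipulation altered the transcriptome relative to wild-type cells. Of 58229 genes in the deposited FPKM table, 36997 to 40521 were listed at 0 in a given library, and 12872 genes with a mean of at least 1 FPKM were tested. Absolute depth was not given in the sources used here. Relative depth, read from the steps between low values, was 27.5% to 41.8% of the OCI wild-type library in the 5 H929 libraries. It was 73.2%, 58.6%, 27.7% and 67.8% in OCI knockdown 1, knockdown 2, overexpression and protein. Of the 5 OCI libraries, 4 were deeper than each H929 library. The p-values of the additive model rest on the spread that cell line and manipulation leave over. That spread holds differences between the lines in a manipulation's effect and differences between the 2 knockdown libraries of a line. It may also be technical, as the labels do not say whether libraries came from separate cultures. Changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and are given ± SE.

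AIMP1 mRNA stood at 14.5 FPKM in H929 wild type and 14.3 FPKM in OCI wild type. It reached 62.5 FPKM in H929 and 59.7 FPKM in OCI overexpression cells, 4.31-fold and 4.17-fold the wild-type level. In knockdown, AIMP1 stood at 24.5% of the wild-type level in H929 knockdown 2, 35.1% in OCI knockdown 1 and 16.4% in OCI knockdown 2. The library labelled H929 AIMP1 knockdown 1 had 14.2 FPKM, 98.2% of the wild-type level. In protein-treated cells AIMP1 mRNA was 20.3 FPKM in H929 and 14.4 FPKM in OCI. The fitted log2 differences were -1.33 ± 0.46 for knockdown (limma adjusted p = 0.980), 2.01 ± 0.53 for overexpression (adjusted p = 0.742) and 0.23 ± 0.53 for protein (adjusted p = 0.837). None of these passed 0.05. Without the H929 wild-type library the protein difference was -0.048. The 11 members of the multi-tRNA synthetase complex, AIMP1 among them, were not called as a list. Their median change was -0.03 in knockdown (camera adjusted p = 0.417), 0.14 in overexpression (0.683) and 0.08 in protein (0.739), where the mean was -0.01 and the direction of the test was down. Adjusted over the list alone, 1 member rose in overexpression, 1 rose and 2 fell in protein, and 0 changed in knockdown. These counts include AIMP1, the manipulated gene, so the member that rose in overexpression need not be another one.

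**Figure D1:**
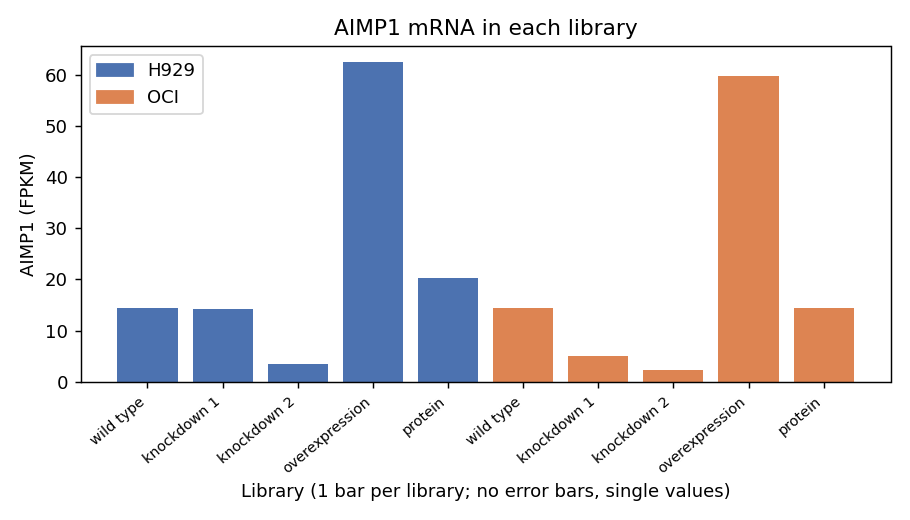
AIMP1 mRNA in FPKM (vertical axis, linear from 0) in each of the 10 libraries, 1 bar per library, coloured by cell line; single values carry no error bars. The overexpression libraries reach 62.5 and 59.7 FPKM, and the library labelled H929 AIMP1 knockdown 1 lies at 14.2 FPKM beside 14.5 FPKM in wild type.

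In cells given AIMP1 protein, the median of NF-kB target genes was higher than in wild-type cells in both lines. camera called the list, but not with an estimated correlation (adjusted p = 0.247), and 13 of 17 members were higher in both lines. TNFAIP3, which encodes the NF-kB inhibitor A20, rose from 2.60 to 32.3 FPKM in H929 and from 3.36 to 29.9 FPKM in OCI, a log2 change of 3.02 ± 0.31 (limma adjusted p = 0.0277; higher in 2 of 2 lines). IL2RG, the gamma chain shared by several interleukin receptors, rose from 2.56 to 17.5 FPKM in H929 and from 31.6 to 168 FPKM in OCI, a change of 2.38 ± 0.28 (adjusted p = 0.0420). These were the 2 genes that limma called higher among 12872, with 0 called lower. At an unadjusted p under 0.05 in limma there were 1702 higher and 745 lower genes, 2447 in all, where 643.6 are expected of unchanged genes. Knockdown against wild type and against overexpression gave 355 and 375, below that number, and overexpression against wild type gave 818. The number is therefore only a rough reference in fits this small. The median change of all tested genes was 0.137, and the medians of called lists are also given relative to it. Both protein libraries stood apart from others of their line. The FPKM sum was 10598200 in H929 protein and 3437320 to 4142480 in the other H929 libraries. The short RNAs RN7SL1, RN7SL2, RN7SK, RMRP and RPPH1 made up 49.6% of the sum in OCI protein and 75.1% to 80.7% in the other OCI libraries. RPS29, RN7SL1, RN7SL2 and RN7SK were listed at 0 in OCI protein, so its share of short RNAs is that of RMRP and RPPH1 alone.

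Of 17 tested NF-kB target genes, 1 was called over all genes, and 13 rose and 0 fell when adjusted over the list alone; 13 were higher in both lines. The list's median was 2.02, or 1.88 relative to all genes, and camera gave an adjusted p = 8.89e-11, against an adjusted p = 0.247 with an estimated correlation. RELB, a subunit of the non-canonical NF-kB pathway, went from 14.7 to 51.6 FPKM in H929 and from 8.95 to 269 FPKM in OCI, and BCL3, an atypical IkB protein, from 5.81 to 24.4 and from 2.16 to 52.6 FPKM. Some markers of other cell types were also higher in both lines. The 4 tested stromal and endothelial markers had a median of 0.78 in H929 and 1.04 in OCI. The 2 myeloid markers had 0.75 and 0.52. The 3 T and NK cell markers went opposite ways, at -0.33 in H929 and 1.48 in OCI. GADD45B had a log2 difference of 2.58 ± 0.43 (adjusted p = 0.0989). MAPK response genes were also higher by camera with a median of 0.43 (adjusted p = 0.0448, and adjusted p = 0.541 with an estimated correlation), with JUN at 5.98 and 75.2 FPKM in H929 and at 3.96 and 82.3 FPKM in OCI. Adjusted over the list alone 7 of its 26 members rose, and over all genes 0 did. Its median was -0.05 in H929 and 0.63 in OCI, and 6 of the 10 fits that left out 1 library lost the call, namely those without either overexpression library, either wild-type library, OCI knockdown 2 or OCI protein. The median was -0.20 without OCI protein, 0.72 without H929 protein, 0.29 with median centring and 0.25 with quantile normalization.

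ATF4 target genes, which serve amino acid supply and the integrated stress response, had a median change of 1.43 in the protein libraries, 0.75 in H929 and 2.21 in OCI. Of 31 members, 0 were called over all genes, and 17 rose and 0 fell when adjusted over the list alone (camera adjusted p = 2.66e-08; adjusted p = 0.541 with an estimated correlation). DDIT3, encoding the stress transcription factor CHOP, had 4.60 and 78.7 FPKM in H929 wild type and protein, and 3.94 and 68.6 FPKM in OCI. SESN2 had a log2 difference of 3.54 ± 0.78 (adjusted p = 0.108) and DDIT4, an inhibitor of mTORC1, 3.07 ± 0.81 (adjusted p = 0.135). Without the OCI protein library the call ended (median 0.86; adjusted p = 0.110). Apoptosis regulators of the BCL2 family had a median of 0.73, with 0 of 13 called over all genes and 6 rising when adjusted over the list alone (camera adjusted p = 8.09e-04; adjusted p = 0.247 with an estimated correlation). The pro-apoptotic genes BBC3 and BMF had differences of 3.16 ± 0.64 and 2.42 ± 0.38. Interferon-stimulated genes had a median of 0.67, with 0 of 17 called over all genes and 8 rising when adjusted over the list alone (camera adjusted p = 0.00136; adjusted p = 0.247 with an estimated correlation). STAT2 went from 12.9 to 58.4 FPKM in H929 and from 9.19 to 45.7 FPKM in OCI.

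In the protein libraries, the 76 cytosolic ribosomal protein genes had a median of 0.76, 72 of them higher in both lines, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 8.54e-12; adjusted p = 0.541 with an estimated correlation). Quantile normalization took their median to 0.06 and ended the call (adjusted p = 0.262). The 34 ribosome biogenesis and MYC target genes had a median of -0.89, with 24 lower in both lines and 0 called over all genes or adjusted over the list alone (camera adjusted p = 2.75e-11; adjusted p = 0.541 with an estimated correlation). NOP16 and NCL, both nucleolar proteins, had differences of -1.60 ± 0.47 and -1.51 ± 0.44. The 32 proteasome subunits had a median of -0.50 (camera adjusted p = 1.46e-08; adjusted p = 0.541 with an estimated correlation), 0 of them called over all genes or adjusted over the list alone, with PSMD1 at 55.1 and 25.6 FPKM in H929 and at 43.8 and 9.43 FPKM in OCI. S phase and DNA replication genes had a median of -0.44, with 1 of 36 rising and 0 falling when adjusted over the list alone (camera adjusted p = 1.65e-04; adjusted p = 0.541 with an estimated correlation). MCM4, a helicase subunit, had a difference of -1.37 ± 0.49, while CDT1, a replication licensing factor, had 1.18 ± 0.32. The median of the S phase list was -0.26 without OCI wild type.

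Genes listed under the unfolded protein response moved both ways in the protein libraries. Of 30 unfolded protein response chaperones, 0 were called over all genes, and 2 rose and 7 fell when adjusted over the list alone (median -0.24; camera adjusted p = 0.00342; adjusted p = 0.541 with an estimated correlation). HSPA5, the major chaperone of the endoplasmic reticulum, had -1.12 ± 0.25, while ERN1, the stress sensor IRE1 alpha, had 3.15 ± 0.73. The chaperone median was -0.15 without H929 protein, -0.15 without H929 wild type, -0.39 with median centring and -0.43 with quantile normalization. Immediate heat shock genes had medians of 0.86 in H929 and -1.56 in OCI. The list was called lower by camera (median -0.24; adjusted p = 0.0443; adjusted p = 0.759 with an estimated correlation), with 0 of 16 members called over all genes or adjusted over the list alone. The call ended without OCI protein, where the median was 0.61, and without OCI wild type, where it was 0.34, and with median centring (median -0.38; adjusted p = 0.0822) and quantile normalization (median -0.47; adjusted p = 0.0646). The median was -1.39 without H929 protein and -0.70 without H929 wild type. HSP90AB1 had 1168 and 752 FPKM in H929 wild type and protein, and 1052 and 293 FPKM in OCI.

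The remaining called lists of this comparison were higher. Mitochondrially encoded mRNAs had a median of 0.91, with 0 of 13 called over all genes and 4 rising when adjusted over the list alone (camera adjusted p = 8.09e-04; adjusted p = 0.541 with an estimated correlation); MT-ND4, a complex I subunit, had 1.37 ± 0.27. Nuclear-encoded oxidative phosphorylation genes had a median of 0.47, with 0 of 38 called over all genes and 9 rising when adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.573 with an estimated correlation). NDUFA2 had 0.96 ± 0.25. Quantile normalization took the medians to 0.34 and 0.20 and ended both calls (adjusted p = 0.0986 and 0.298), and so did leaving out OCI wild type, which took the mitochondrial median to 0.46. The oxidative phosphorylation call also ended with median centring (adjusted p = 0.0503) and without H929 protein. Mature B cell genes had a median of 0.76, with 0 of 11 called over all genes and 2 rising when adjusted over the list alone (camera adjusted p = 0.0486; adjusted p = 0.542 with an estimated correlation), CD74 at 0.634 and 9.46 FPKM in H929 and at 1.21 and 37.6 FPKM in OCI. That call was lost in 6 of 10 fits that left out 1 library, among them those without H929 protein, OCI wild type and either OCI knockdown library or either overexpression library. The median was 0.17 without OCI wild type, 0.43 without H929 protein, 1.34 without H929 wild type and 1.15 without OCI protein. Relative to all genes, the medians of the higher lists were 0.29 for MAPK response, 1.29 for ATF4 targets, 0.59 for apoptosis regulators, 0.53 for interferon-stimulated genes, 0.62 for ribosomal proteins, 0.77 for mitochondrial mRNAs, 0.33 for oxidative phosphorylation and 0.62 for mature B cell genes. Those of the lower lists were -1.03 for ribosome biogenesis, -0.64 for the proteasome, -0.58 for S phase, -0.38 for unfolded protein response chaperones and -0.38 for heat shock.

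**Figure D2:**
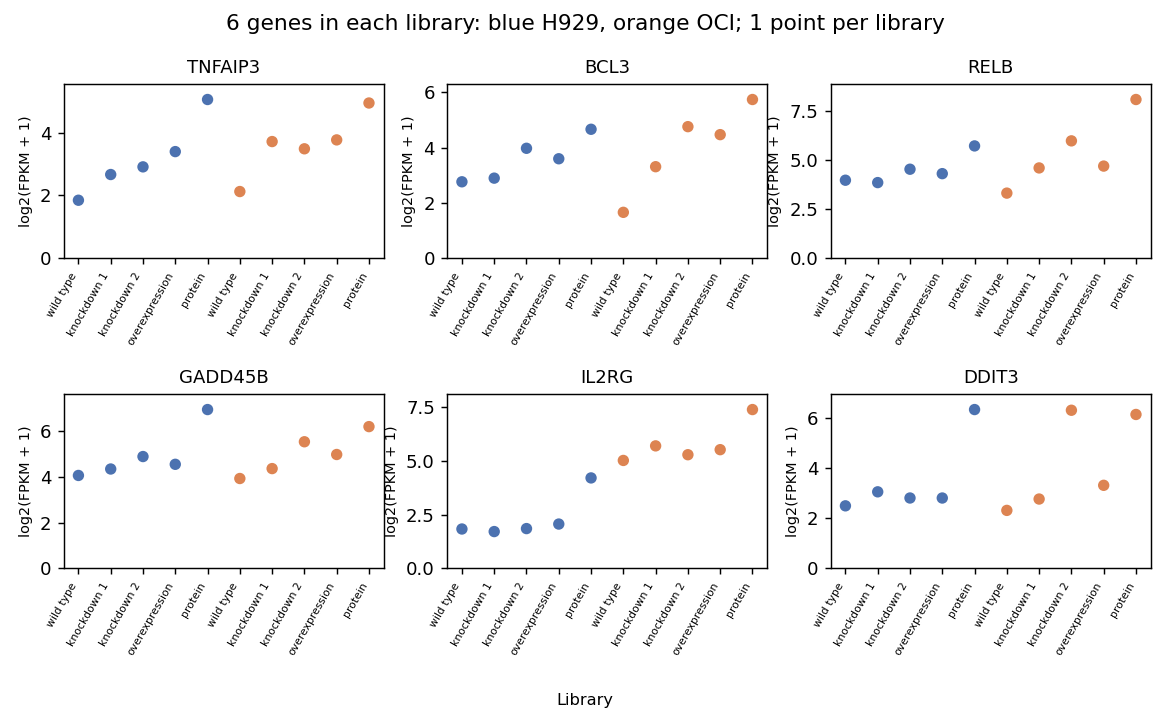
Expression of 6 genes, as log2(FPKM + 1) on axes that start at 0, in each of the 10 libraries (1 point per library, blue H929, orange OCI). TNFAIP3 and IL2RG passed the limma test for protein against wild type; BCL3, RELB, GADD45B and DDIT3 did not. DDIT3 stands at 77.2 FPKM in OCI knockdown 2 and at 5.75 FPKM in OCI knockdown 1.

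Further genes with the same sign in both lines, none past the threshold, were JUN (3.76 ± 0.71), TSC22D3, a glucocorticoid-induced leucine zipper protein (3.70 ± 0.83), CLIC4 (3.11 ± 0.39, adjusted p = 0.0541) and the stress transcription factor ATF3 (2.95 ± 0.72) among higher genes. Among lower genes were DDN (-2.25 ± 0.63), TNFRSF8, the receptor CD30 (-2.48 ± 0.48), and the long non-coding RNA SNHG26 (-2.08 ± 0.42). Small RNA genes and pseudogenes such as SNORA74B, RNVU1-7, RNU2-63P, CDC26P1, SNRPGP15 and SUMO2P21 were listed at 0 in some libraries and share sequence with other copies, so they carry no fold. The calls of TNFAIP3 and IL2RG both ended when either H929 knockdown library (one of them the library labelled H929 AIMP1 knockdown 1), either overexpression library or either wild-type library was left out, and with quantile normalization, the 8 group means and no term for the line. IL2RG also lost its call with median centring and with eBayes without a trend. Over all alternatives the adjusted p ranged from 0.0111 to 0.196 for TNFAIP3 and from 0.0193 to 0.597 for IL2RG. The number of called genes was 0 without the library labelled H929 AIMP1 knockdown 1 or H929 knockdown 2, 1 without H929 overexpression, OCI overexpression or OCI wild type, 5 without H929 wild type, 21 without OCI protein, 30 without H929 protein, 31 without OCI knockdown 1 and 548 without OCI knockdown 2.

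In cells overexpressing AIMP1, mitochondrially encoded mRNAs were higher than in wild-type cells of both lines. MT-ND5, a complex I subunit, went from 271 to 1026 FPKM in H929 and from 139 to 847 FPKM in OCI, a log2 difference of 2.25 ± 0.25, with an adjusted p of 0.0610 that missed the threshold. limma called 0 of 12872 genes, with 506 higher and 312 lower at an unadjusted p under 0.05, 818 in all. Of 13 mitochondrial mRNAs, 0 were called over all genes and 11 rose when adjusted over the list alone, 12 being higher in both lines (median 2.002, at 1.12 in H929 and 2.59 in OCI, and mean 1.63; camera adjusted p = 8.95e-20; adjusted p = 0.109 with an estimated correlation). The FPKM sum was 7890140 in OCI overexpression, apart from the 3837400 to 4922090 of OCI wild type, protein and knockdown 1. MT-ND4L had 2.20 ± 0.34 and MT-ND2 2.15 ± 0.39. Interferon-stimulated genes had a median of 0.67, with 0 of 17 called over all genes and 6 rising when adjusted over the list alone (camera adjusted p = 5.96e-07; adjusted p = 0.0908 with an estimated correlation). IFI6 went from 1.61 to 9.38 FPKM in H929 and from 2.33 to 9.37 FPKM in OCI, and IRF9 had 1.53 ± 0.39. NF-kB target genes had a median of 0.77, with 0 of 17 called over all genes and 1 rising when adjusted over the list alone (camera adjusted p = 6.09e-06; adjusted p = 0.450 with an estimated correlation); TNFAIP3 had 1.60 ± 0.31 and BCL3 1.82 ± 0.61. The NF-kB median was 0.38 in H929 and 1.05 in OCI, and 0.31 without OCI wild type. Stromal and myeloid markers, 4 and 2 tested genes, had medians of 0.47 and 0.92.

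Mature B cell genes had a median of 0.81 in overexpression cells, with 0 of 11 called over all genes or adjusted over the list alone (camera adjusted p = 4.82e-04; adjusted p = 0.450 with an estimated correlation). HLA-DRA, a class II antigen presentation gene, had 4.43 and 85.1 FPKM in OCI and 0.249 and 1.24 FPKM in H929. The list's median was 0.47 in H929 and 1.14 in OCI, 1.22 without H929 wild type and 1.26 without OCI overexpression. Cytosolic ribosomal proteins had a median of 0.32, with 0 of 76 called either way (camera adjusted p = 3.03e-07; adjusted p = 0.694 with an estimated correlation), RPS27 at 0.92 ± 0.36; quantile normalization took the median to 0.09 and ended that call (adjusted p = 0.0673). The ribosomal median was 0.50 without H929 overexpression, 0.17 without OCI overexpression and 0.18 without OCI wild type. The lower lists had 0 members called over all genes or adjusted over the list alone. Ribosome biogenesis and MYC target genes had a median of -0.51 with 29 of 34 lower in both lines (camera adjusted p = 1.01e-07; adjusted p = 0.600 with an estimated correlation), POLR1B at -1.35 ± 0.42; the median was -0.81 without OCI overexpression. S phase and DNA replication genes had a median of -0.36 with 30 of 36 lower in both lines (camera adjusted p = 6.02e-06; adjusted p = 0.600 with an estimated correlation), the methylation maintenance gene UHRF1 at -1.31 ± 0.70. Cholesterol and fatty acid synthesis genes had a median of -0.33 (camera adjusted p = 0.00128; adjusted p = 0.694 with an estimated correlation), the desaturase SCD at -1.28 ± 0.40. Proteasome subunits had a median of -0.28 (camera adjusted p = 0.00129; adjusted p = 0.694 with an estimated correlation) and the ANP32 family and histone acetylation regulators -0.16 (camera adjusted p = 0.0168; adjusted p = 0.450 with an estimated correlation), the acetyltransferases EP300 and KAT5 at -0.94 ± 0.42 and -0.85 ± 0.32. The last 3 lists lost the call without H929 overexpression or OCI wild type, and the acetylation list also with quantile normalization (median -0.08; adjusted p = 0.125). Leaving out H929 overexpression, H929 wild type, OCI overexpression and OCI wild type in turn, the cholesterol median was -0.15, -0.81, -0.56 and 0.15. The proteasome median was -0.11, -0.46 and -0.18 without H929 overexpression, OCI overexpression and OCI wild type, and that of the acetylation list -0.24, -0.26 and -0.26 without H929 wild type, OCI overexpression and OCI wild type.

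Further differences in overexpression cells that did not pass were those of TXNIP, which binds thioredoxin, from 22.3 to 156 FPKM in OCI and to 116 FPKM in H929, YPEL3 (2.38 ± 0.75), H4C12 (3.18 ± 1.15) and the class II chaperone CD74 (2.32 ± 0.74). Lower values that did not pass were those of the phosphatase PTPN7 (-2.10 ± 0.76), DDN (-1.90 ± 0.63) and the chemokine receptor CXCR3 (-1.61 ± 0.74). DNAJC27-AS1, STIM2-AS1, LINC02608, LINC01229, RNU2-63P, SUMO2P1 and 5 RN7SL pseudogenes also met the naming rule; most were listed at 0 in some libraries. Histone and RN7SL genes have near-identical copies, and strand was not stated for the antisense genes, so these values are uncertain. The number of called genes was 5 without H929 overexpression or H929 wild type, 4 without OCI knockdown 2, 3 without OCI overexpression, and 1 without OCI knockdown 1 or OCI wild type.

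In the 4 knockdown libraries, mitochondrially encoded mRNAs were also higher than in wild type, although AIMP1 was not lower in the library labelled H929 AIMP1 knockdown 1. limma called 0 of 12872 genes; 355 had an unadjusted p under 0.05, 270 higher and 85 lower, where 643.6 are expected by chance. Of the 13 mitochondrial mRNAs, 12 were higher in all 4 libraries, and 10 rose when adjusted over the list alone, with 0 called over all genes (median 1.07; camera adjusted p = 5.88e-14; adjusted p = 0.217 with an estimated correlation). MT-ND5 had 1.26 ± 0.22 and MT-ND2 1.23 ± 0.34. Cytosolic ribosomal protein genes had a median of 0.30, with 48 of 76 higher in all 4 libraries (camera adjusted p = 2.18e-09; adjusted p = 0.572 with an estimated correlation); quantile normalization took the median to 0.08. Interferon-stimulated genes had a median of 0.42 (camera adjusted p = 5.31e-06; adjusted p = 0.147 with an estimated correlation), IRF9 at 1.17 ± 0.34. NF-kB target genes had a median of 0.66 with 1 of 17 rising when adjusted over the list alone (camera adjusted p = 1.88e-07; adjusted p = 0.251 with an estimated correlation), TNFAIP3 at 1.21 ± 0.27 and BCL3 at 1.52 ± 0.53. The NF-kB median was 0.02 in the library labelled H929 AIMP1 knockdown 1, 0.42 in H929 knockdown 2, 0.75 in OCI knockdown 1 and 1.33 in OCI knockdown 2. Mature B cell genes had a median of 1.04, with 5 of 11 rising when adjusted over the list alone (camera adjusted p = 2.98e-05; adjusted p = 0.304 with an estimated correlation), HLA-DPA1 at 41.3 and 60.3 FPKM in the OCI knockdown libraries and 0.847 FPKM in OCI wild type. In the same 4 libraries that list's median was 0.10, 0.23, 0.81 and 1.92. The 4 stromal and 2 myeloid markers tested had medians of 0.61 and 0.36. Apoptosis regulators had a median of 0.26 (camera adjusted p = 7.36e-04; adjusted p = 0.251 with an estimated correlation), BMF at 1.11 ± 0.33. The FPKM sum was 7427740 in OCI knockdown 2, beside 4922090 in OCI knockdown 1 and 4441060 in OCI wild type. In each of these 6 lists 0 members were called over all genes, and in those not given a count 0 were called adjusted over the list alone. Leaving out OCI wild type took the medians to 0.59 for mitochondrial mRNAs, 0.16 for ribosomal proteins, 0.17 for NF-kB targets, 0.37 for mature B cell genes and 0.16 for apoptosis regulators. Leaving out OCI knockdown 2 took those of ribosomal proteins and mature B cell genes to 0.17 and 0.67.

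ATF4 target genes differed between the knockdown libraries. Their medians were 0.47 in the library labelled H929 AIMP1 knockdown 1, 0.28 in H929 knockdown 2, -0.19 in OCI knockdown 1 and 1.40 in OCI knockdown 2. The list was called higher by camera (median 0.51; adjusted p = 5.31e-06; adjusted p = 0.566 with an estimated correlation), with 0 of 31 called over all genes or adjusted over the list alone. Of members that the naming rule took, ASNS, which makes asparagine, stood at 315 and 42.0 FPKM in OCI knockdown 2 and knockdown 1. DDIT4 stood at 531 and 51.3 FPKM and DDIT3 at 77.2 and 5.75 FPKM. These libraries were set beside each other after the values were seen. OCI knockdown 1 lay close to OCI wild type (r = 0.974 across genes), and OCI knockdown 2 less so (r = 0.910); genes are not independent replicates. Ribosome biogenesis and MYC target genes had a median of -0.48, at -0.24, -0.35, -0.10 and -1.21 in the same 4 libraries (camera adjusted p = 5.36e-10; adjusted p = 0.444 with an estimated correlation). S phase genes had -0.35 (camera adjusted p = 3.66e-07; adjusted p = 0.450 with an estimated correlation), proteasome subunits -0.32 (3.32e-06; adjusted p = 0.566 with an estimated correlation), cholesterol and fatty acid synthesis -0.40 (3.95e-06; adjusted p = 0.450 with an estimated correlation), heat shock genes -0.39, with -1.22 in OCI knockdown 2 (0.0102; adjusted p = 0.685 with an estimated correlation) and unfolded protein response chaperones -0.19 (0.0109; adjusted p = 0.450 with an estimated correlation). Over the library labelled H929 AIMP1 knockdown 1, H929 knockdown 2, OCI knockdown 1 and OCI knockdown 2, the medians were -0.26, -0.25, -0.07 and -0.92 for S phase genes, -0.07, -0.15, -0.06 and -0.91 for the proteasome, and 0.01, 0.03, -0.68 and -0.96 for cholesterol and fatty acid synthesis. Leaving out OCI knockdown 2 gave medians of 0.23 for ATF4 targets, -0.20 for ribosome biogenesis, -0.16 for S phase, -0.087 for the proteasome, -0.26 for cholesterol synthesis and -0.16 for heat shock. Leaving out OCI wild type gave 0.25 for ATF4 targets, -0.23 for S phase, -0.20 for the proteasome, -0.017 for cholesterol synthesis and 0.025 for heat shock. The ATF4 median was 0.89 without OCI knockdown 1, and without H929 wild type the cholesterol and heat shock medians were -0.82 and -0.72. For these 6 lists, 0 members were called over all genes or adjusted over the list alone. ODC1, the rate-limiting enzyme of polyamine synthesis, had -1.03 ± 0.45, TYMS -0.75 ± 0.46, HSPA5 -0.51 ± 0.21 and PSMD11 -0.72 ± 0.36.

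Further genes with the same sign in all 4 knockdown libraries, none past the threshold, were the adaptor HSH2D (1.49 ± 0.31), TRANK1 (1.49 ± 0.31), the kinase SGK1 (1.38 ± 0.27), ADAP2 (1.54 ± 0.50), DNAAF3 (1.39 ± 0.43) and the cytidine deaminase APOBEC3H (1.59 ± 0.60) among the higher ones. Lower ones were NRIP1, a nuclear receptor corepressor (-1.08 ± 0.32), NREP (-1.03 ± 0.37), PAPSS2 (-0.98 ± 0.35), ADGRA3 (-1.10 ± 0.49), PLD4 (-0.87 ± 0.43) and LPCAT1 (-0.73 ± 0.39). Without OCI wild type, 6 of the 13 called lists lost the call (apoptosis regulators, ATF4 targets, cholesterol synthesis, heat shock, mature B cell and NF-kB targets), and 8 lists were called in all. Heat shock genes also lost it without OCI knockdown 2, and unfolded protein response chaperones without H929 knockdown 2, H929 wild type or OCI knockdown 1 and with quantile normalization (adjusted p = 0.0767). Called genes numbered 5 without H929 wild type, 2 without OCI knockdown 1, and 1 without H929 knockdown 2, either overexpression library or OCI wild type.

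Set directly against each other, knockdown cells had less mitochondrially encoded mRNA than overexpression cells. AIMP1 differed by -3.34 ± 0.46 (limma adjusted p = 0.246; lower in 4 of 4 libraries); without the library labelled H929 AIMP1 knockdown 1 the difference was -3.76 and past the threshold. limma called 0 genes, with 167 higher and 208 lower at an unadjusted p under 0.05, 375 in all. ANXA1, a phospholipid-binding protein, had -2.31 ± 0.33 (adjusted p = 0.246), with 1.77 to 3.08 FPKM in wild type and 9.40 and 14.5 FPKM in overexpression. RBMS3 (-1.63 ± 0.39), PCDH18 (-1.64 ± 0.44), HEY1 (-1.40 ± 0.45) and MECOM (-1.13 ± 0.37) were lower without passing, and EGR1 (1.67 ± 1.23), CD52 (1.42 ± 0.37), PTPRJ (1.32 ± 0.33), HOXB9 (1.25 ± 0.52) and ITGAL (1.24 ± 0.35) higher without passing. Mitochondrial mRNAs had a median of -0.91, with 0 of 13 called over all genes and 7 falling when adjusted over the list alone (camera adjusted p = 1.25e-14; adjusted p = 0.361 with an estimated correlation). ATF4 targets had a median of 0.61, at 0.69, 0.44, -0.35 and 1.47 in the library labelled H929 AIMP1 knockdown 1, H929 knockdown 2, OCI knockdown 1 and OCI knockdown 2 (camera adjusted p = 3.84e-07; adjusted p = 0.949 with an estimated correlation), ATF4 itself at 0.91 ± 0.37. The ATF4 list's median was 0.19 without OCI knockdown 2 and 0.39 without OCI overexpression, and the mitochondrial median was -0.44 without OCI overexpression.

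The other 4 called lists of this comparison were interferon-stimulated genes (-0.35; camera adjusted p = 0.0136; adjusted p = 0.361 with an estimated correlation), aminoacyl-tRNA synthetases outside the complex (0.37; 0.0151; adjusted p = 0.949 with an estimated correlation), ANP32 family and histone acetylation regulators (0.12; 0.0245; adjusted p = 0.567 with an estimated correlation) and mitosis genes (-0.10; 0.0463; adjusted p = 0.949 with an estimated correlation). In these and in the ATF4 list 0 members were called over all genes or adjusted over the list alone. YARS1, a tRNA synthetase, had 0.57 ± 0.25, KAT5 0.75 ± 0.28, DTX3L -0.80 ± 0.36 and HMMR -0.91 ± 0.52. Each of these 4 lists lost the call without H929 overexpression. The synthetases, the acetylation regulators and mitosis also lost it without the library labelled H929 AIMP1 knockdown 1, the first 2 without OCI overexpression, the regulators without OCI knockdown 1 and mitosis without OCI knockdown 2. Quantile normalization ended the calls of the synthetases and the regulators (adjusted p = 0.0657 for both). The interferon median was -0.20 without OCI knockdown 1. That of the regulators was 0.18, 0.20 and 0.23 without OCI knockdown 1, OCI knockdown 2 and OCI overexpression, where that of mitosis was -0.21, -0.0044 and -0.20, and without H929 overexpression mitosis had -0.038. With quantile normalization its median was -0.17. Called genes numbered 7 without H929 overexpression, 2 without OCI overexpression and 1 without either H929 knockdown library or OCI knockdown 1; called lists numbered 3 without the library labelled H929 AIMP1 knockdown 1 and 11 without OCI knockdown 2.

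**Figure D3:**
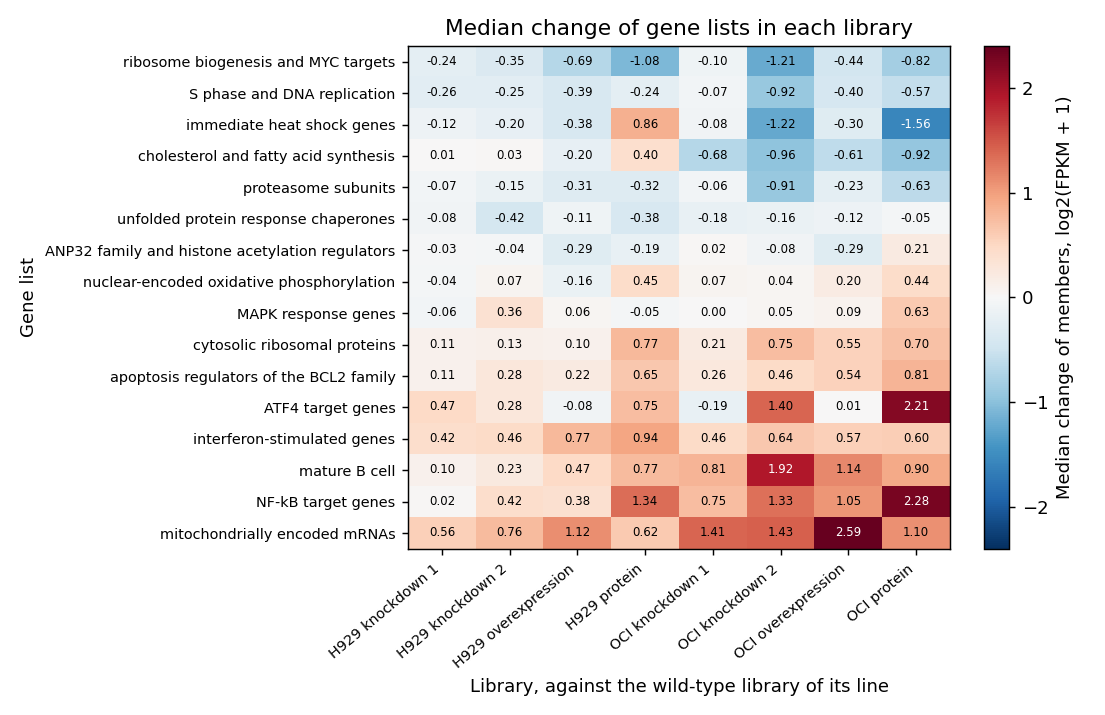
Median log2(FPKM + 1) change of the members of each gene list (vertical axis) in each manipulated library against the wild-type library of its line (horizontal axis); red is higher, blue lower, and each cell prints its median. NF-kB target genes are highest in the protein libraries, at 1.34 in H929 and 2.28 in OCI, and ATF4 target genes reach 1.40 in OCI knockdown 2 and -0.19 in OCI knockdown 1.

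The 3 comparisons with wild type pointed partly the same way. Across genes, the changes correlated at r = 0.694 for knockdown with overexpression, 0.638 for knockdown with protein and 0.540 for overexpression with protein. Simulations of the same design with no change, in which all 10 libraries were independent noise, gave 0.578, 0.575 and 0.499. They account for the sharing of wild-type libraries, but not for the actual deviations of those libraries. The covariances were 0.157, 0.191 and 0.212, beside 0.0972, 0.0966 and 0.0968 in the simulations, differences of 0.0600, 0.0945 and 0.115. Of the lists called higher, 5 were shared by knockdown and overexpression where 1.35 are expected of independent lists, 7 by knockdown and protein (2.42) and 5 by overexpression and protein (1.73). Of those called lower, 4 (1.15), 5 (1.15) and 3 (0.962) were shared. These are calls of camera at the preset correlation, and with an estimated correlation 0 lists were called in each of the 3 comparisons. With 1 wild-type library per line the controls could not be split, so part of the excess may come from the shared controls. The expectations for lists leave out those controls, and no simulated value was computed for shared lists. Between lines, which share no library, the same manipulation correlated at r = 0.281 for knockdown, 0.240 for overexpression and 0.263 for protein. Unmatched manipulations correlated at 0.141 to 0.393 with a median of 0.259 (SD 0.0946, 6 pairs), so the matched values lay within that range. With knockdown number 1 alone, which includes the library labelled H929 AIMP1 knockdown 1, the knockdown value was 0.0852.

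OCI and H929 cells differed in many genes. limma called 1658 of 12872 genes, 978 higher and 680 lower in OCI, and 3785 had an unadjusted p under 0.05. S100A4, a calcium-binding protein, was 326 to 491 FPKM in the OCI libraries and 0.700 to 1.33 FPKM in the H929 libraries (log2 difference 7.76 ± 0.16, adjusted p = 5.23e-09; higher in 5 of 5 matched pairs). CST3 and the DNA repair enzyme MGMT were listed at 0 in all H929 libraries, with 74.0 to 150 FPKM and 16.2 to 33.0 FPKM in OCI. ICAM3 (5.23 ± 0.25), PTPRCAP (4.69 ± 0.43), ZNF544 (4.54 ± 0.27) and the class II gene HLA-DRA (4.68 ± 0.53) were higher in OCI. H2BC13, H2AC16 and HBE1 were higher too, HBE1, an embryonic globin, being listed at 0 in H929. GPR15, a chemoattractant receptor, was 123 to 217 FPKM in H929 and at most 0.0530 FPKM in OCI (-7.42 ± 0.20, adjusted p = 3.31e-08). COL6A3 (-4.28 ± 0.29), IL32 (-4.14 ± 0.21), CD52 (-3.77 ± 0.27), MAGEA6 (-3.70 ± 0.21), MYOF (-3.45 ± 0.24), TEX19 (-3.22 ± 0.49), the mitochondrial enzyme IDH2 (-3.07 ± 0.34) and NXN (-2.77 ± 0.44) were lower in OCI, and DSCR8 was listed at 0 there with 75.3 to 258 FPKM in H929.

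By list, mature B cell genes were higher in OCI, with 6 of 11 members called over all genes and 7 adjusted over the list alone (median 0.93; camera adjusted p = 0.00285; adjusted p = 0.802 with an estimated correlation). Plasma cell identity genes had 4 of 23 called higher over all genes and 5 adjusted over the list alone (median 0.38; camera adjusted p = 0.0397; adjusted p = 0.802 with an estimated correlation), among them SLAMF7 (2.71 ± 0.42), GPRC5D (2.23 ± 0.43) and TNFRSF17, the receptor BCMA (1.46 ± 0.34). ATF4 targets had 2 of 31 called both over all genes and adjusted over the list alone (median 0.69; camera adjusted p = 3.18e-04; adjusted p = 0.802 with an estimated correlation), STC2 (1.97 ± 0.46) and PHGDH (1.69 ± 0.32). Replication-dependent histones had 5 of 17 called both ways (median 0.50; camera adjusted p = 0.00299; adjusted p = 0.802 with an estimated correlation), H2AC4 at 3.62 ± 0.42. Mitochondrial mRNAs were lower in OCI, 6 of 13 called over all genes and 8 adjusted over the list alone (median -0.71; camera adjusted p = 7.42e-04; adjusted p = 0.802 with an estimated correlation), MT-ND2 at -1.23 ± 0.25. Mitosis genes had 4 of 36 called lower both ways (median -0.27; camera adjusted p = 0.0313; adjusted p = 0.802 with an estimated correlation), ANLN at -1.10 ± 0.22. Heat shock genes had 1 higher and 1 lower of 16 over all genes, and 1 and 2 adjusted over the list alone (median -0.42; camera adjusted p = 0.0469; adjusted p = 0.802 with an estimated correlation), AHSA1 at -1.23 ± 0.26. Some matched pairs went against the call of their list. In the wild-type, overexpression, protein, knockdown 1 and knockdown 2 pairs the medians were 0.24, 0.09, -1.99, 0.34 and -0.95 for heat shock and 0.22, -0.41, -0.64, 0.01 and -0.38 for mitosis. ATF4 targets and plasma cell genes had -0.29 and -0.15 in the knockdown 1 pair, and histones -0.35 in the knockdown 2 pair. MYC (1.45 ± 0.26), CCND2 (1.29 ± 0.28), CDKN1A (1.81 ± 0.37), BIK (2.54 ± 0.22) and FADS1 (2.11 ± 0.25), members of lists not called as such, were higher in OCI. RRM2 (-1.13 ± 0.22) was lower.

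In 4 of the 5 matched pairs the OCI library was the deeper one, and in the overexpression pair it was the shallower one, at 27.7% beside 33.9% of the OCI wild-type depth. Called genes numbered 952 without the library labelled H929 AIMP1 knockdown 1, 1082 without H929 knockdown 2, 808 and 800 without H929 and OCI overexpression, and 812 and 815 without H929 and OCI wild type. Called lists numbered 4 without H929 knockdown 2, 12 without H929 wild type, 13 without OCI knockdown 1 and 11 without OCI wild type, beside 7 with all libraries. Mitosis, plasma cell identity, heat shock and histone lists each lost the call without H929 protein or OCI protein, the first 3 also without H929 knockdown 2 or OCI knockdown 2, and mitosis also without either overexpression library. Plasma cell identity lost it with quantile normalization (median 0.19; adjusted p = 0.141), which took the histone median to 0.27. Leaving out either protein library gave medians of 0.015 for heat shock, -0.14 for mitosis, 0.25 for plasma cell identity and 0.22 for histones, and leaving out OCI protein 0.43 for ATF4 targets. The heat shock median was -0.63 without either overexpression library, that of mitosis -0.42 without either wild type, and that of mature B cell genes 1.76 without OCI overexpression.

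Whether a manipulation acted differently in the 2 lines was tested with 8 group means, where each lone library was assumed to vary like the knockdown pairs. limma called 0 genes for knockdown (162 at an unadjusted p under 0.05), 1 for overexpression (299) and 13 for protein (899), 2 with a higher and 11 with a lower change in OCI. In simulated data of this design, 4 unchanged genes were called for overexpression and 2 for protein, and 0% of genes with a log2 change of 2 were recovered in either. Of these calls, RNVU1-7 for overexpression and 12 of 13 genes for protein were listed at 0 in some library, and 11 of the 13 were not protein-coding. RN7SL1, RN7SL2 and RN7SK, abundant short non-coding RNAs, and RPS29 were listed at 0 in OCI protein alone, with 4186 to 15010 FPKM for RPS29 in the 9 other libraries. RNU1-4 and RNVU1-28, U1 small nuclear RNA genes, and 7SK were the other named calls. Without any 1 of the 4 knockdown libraries, 0 genes were called for overexpression and protein.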

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

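The test of other splits of the libraries was set before its result was seen, and the other tests of this part were chosen after the results were seen.

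Changes against wild type pointed partly the same way in knockdown, overexpression and protein, and between lines, which share no library, 54.2% to 66.5% of genes had the same sign. Opposite effects of lower and higher AIMP1 mRNA would by themselves give negative correlations of knockdown with overexpression. The 3 knockdown libraries with lower AIMP1 correlated with overexpression in the other line at r = 0.128, 0.212 and 0.346. These values restate the pattern, so they do not exclude opposite effects beneath a change shared for another reason. Like effects of either change of level are not covered. Chance values of the wild-type libraries stay open: the lowest of the 9 correlations between lines was 0.141, but each line has 1 wild-type library. Wild-type libraries handled apart from the others cannot be told apart from an effect of manipulation either, since the wild types of the lines correlated at r = 0.938 and other matched pairs at 0.848 to 0.931. A response common to all manipulations remains a candidate explanation, untested here.

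NF-kB target genes were higher in the protein libraries by camera and by fry (adjusted p = 0.00963), but camera lost the call with an estimated correlation (adjusted p = 0.247). Scaling is argued against by a median of 1.84 above that of all genes with quantile normalization. Cells of another type cannot be told apart from it, since few markers lay above the floor. The highest marker list median was 0.748 FPKM in OCI protein, and each such median was 0 in H929 protein. Stromal and myeloid markers had median changes of 0.75 and 0.64. The myeloid marker CTSS went from 11.4 to 16.5 FPKM in H929 and from 6.83 to 10.9 FPKM in OCI. CTSS was above wild type in the other manipulations too, at 18.1 and 15.8 FPKM in H929 and OCI overexpression and 11.3 to 17.6 FPKM in the knockdown libraries. In H929, the line with the lower value, the list stood 1.15 above the mean of knockdown and overexpression. A shared change of equal size in all manipulated libraries does not account for that. A shared change that was stronger in the protein libraries is not excluded. A response to the protein may be the cause, as a hypothesis, and whether AIMP1 or another constituent of the added protein acted was not tested.

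AIMP1 was not lower in the library labelled H929 AIMP1 knockdown 1. A swap with another library of the series is argued against by the lowest AIMP1 level among libraries not labelled knockdown, 14.3 FPKM, since none is as low as the other knockdown libraries (at most 5.03 FPKM). Wild-type cells under a wrong label cannot be told apart from an ineffective knockdown: that library correlated with H929 wild type at r = 0.969, and H929 knockdown 2 at 0.967.

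The difference between OCI and H929 was set beside other splits of the 10 libraries. Of 100 splits drawn from 126, only the real one gave 1658 genes, and the highest other gave 41. In the other splits the difference between the lines largely stayed in the spread, which lowers their counts. The test therefore cannot say how many genes chance alone would give.

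The test of a difference between the lines called 1 gene with overexpression and 13 with protein, where simulated data gave 4 and 2 false calls and 0% recovery at a log2 change of 2. The fitted difference was 12.29 for RNVU1-7 with overexpression. With protein it was 11.35 for RNU1-4, 9.85 for RNVU1-28, -22.24 for RN7SL1, -21.36 for RN7SL2, -20.64 for RN7SK, -14.61 for RPS29 and -11.17 for 7SK. Each is listed at 0 in some library, so these values are set by the pseudocount and give no fold. Among lists called by camera, opposite medians in the lines, OCI minus H929, were -0.85 for cholesterol and fatty acid synthesis in knockdown (0.02 in H929, -0.82 in OCI), -2.42 for heat shock genes in protein (0.86 and -1.56) and 0.68 for MAPK response genes in protein (-0.05 and 0.63). Lists that were not called had opposite signs too, in protein for example cholesterol synthesis (0.40 in H929, -0.92 in OCI), histones (-0.47 and 0.73) and mitosis (0.70 and -0.29). None of these differences was tested.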

How the results depend on the processing

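The alternatives restricted to genes above 0 in every library and to protein-coding genes were chosen after seeing the data, and the others before the data were examined. Over 7419 alternatives of 349 named results, 6917 kept direction and side of the threshold, 359 lost the threshold, 137 passed it and 6 reversed. Results not past the threshold count as kept where they stayed so with the same sign. Past it were 85 named results of OCI against H929 and 2 of protein. Of these, 31 and 0 kept the call in every alternative. Absolute depth is not known, and 1 library per group outside knockdown limits the calls. The cause was not tested for the changes below.

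With 8 group means, calls numbered 3 for knockdown, 12 for protein, 4 for knockdown against overexpression and 844 for OCI against H929. With no filter on low values they were 11 for knockdown, 17 for overexpression, 14 for protein, 6 for knockdown against overexpression and 1063 for OCI against H929 (11 lists), and 633, 1289 and 1425 for knockdown, overexpression and protein by line. A mean of at least 5 FPKM gave 1 for overexpression, 4 for protein, and 4 and 8 for knockdown and overexpression by line. Median centring gave 1 for protein, and 4 and 8 for knockdown and overexpression by line. Quantile normalization gave 1 for overexpression and 0 for protein, where 2447 genes had an unadjusted p under 0.05 in limma without that scaling. Moderation without a trend gave 4 and 6 for knockdown and overexpression by line, and robust moderation 2 and 6, with 1 for overexpression. Without a term for the line limma called 0 genes for protein. A pseudocount of 0.1 gave 0 for overexpression by line and 7 for protein by line.

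Genes above 0 in every library gave 1 call for overexpression, 0 for overexpression by line and 2 for protein by line, and a correlation of the overexpression change between lines of 0.365. Protein-coding genes alone gave 1 for overexpression, 4 for protein, 0 and 3 for overexpression and protein by line, and 0.382 for that correlation, which was 0.347 with Spearman. With knockdown number 1 alone the knockdown correlation was 0.0852. Lists called with an estimated correlation numbered 0 for knockdown, 0 for overexpression, 0 for protein, 0 for knockdown against overexpression and 0 for OCI against H929. In that order fry called 0, 2, 3, 0 and 1. In overexpression these were mitochondrial mRNAs (fry adjusted p = 0.0197) and interferon-stimulated genes (0.0260). In protein they were NF-kB targets and interferon-stimulated genes (0.00963 for both) and apoptosis regulators (0.0120). In OCI against H929 fry called apoptosis regulators (0.0379), which camera did not call.

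The knockdown number as a replicate block gave an AIMP1 difference of -3.34 between knockdown and overexpression that passed the threshold (limma adjusted p = 0.0218), and 1 call for that comparison, 1 for overexpression, 7 for protein and 7 for overexpression by line. The numbers were not taken to pair libraries, which 2 pairs cannot settle: the difference of knockdown 2 and 1 correlated at 0.0757 between the lines, and in both lines AIMP1 was lower in knockdown 2 (3.55 and 2.35 FPKM) than in knockdown 1 (14.2 and 5.03 FPKM).

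Leaving out each library in turn gave 0 to 5 genes for knockdown, 0 to 5 for overexpression, 0 to 548 for protein, 0 to 7 for knockdown against overexpression, 800 to 1712 for OCI against H929, 0 in each of the 8 fits with both wild types for knockdown by line, and, in the 6 fits that could be made for each, 0 to 1 for overexpression by line and 0 to 13 for protein by line. Lists numbered 8 to 13, 8 to 14, 10 to 16, 3 to 11 and 4 to 13 in the 5 comparisons. AIMP1 ranged from -1.75 to -1.05 for knockdown, 1.73 to 2.29 for overexpression, -0.048 to 0.51 for protein and -3.76 to -3.09 for knockdown against overexpression. Without the tenth of genes that differ most between the lines, the correlation between lines was 0.316 for knockdown, 0.310 for overexpression and 0.322 for protein. AIMP1 was counted apart from the 349 named results, and its sign in protein reversed without H929 wild type (-0.048). The 6 reversals among the named results came without OCI overexpression for MT-ND3 and without OCI wild type for 5 genes. The ranges were, for knockdown vs wild type: BCL2L1, -0.0544 to 0.36, for knockdown vs wild type: HSPH1, -1.53 to 0.0352, for knockdown vs wild type: FKBP4, -0.9998 to 0.0078, and for knockdown vs wild type: ICAM1, -0.0880 to 1.54. They were -0.22 to 2.98 for protein vs wild type: HLA-DRA, and -1.97 to 0.0023 for knockdown vs overexpression: MT-ND3.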

Other observations

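The values in this part were chosen after they were seen, except those of the gene lists, EGR1 and HBE1, which the report also gives.

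NSD2 and FGFR3 lie at a translocation breakpoint known in myeloma. NSD2 stood at 61.9 to 101 FPKM over all 10 libraries and FGFR3 at 0.241 to 1.43 FPKM; the identity of the line labelled H929 was not checked here. MAF, another myeloma translocation gene, ranged from 53.3 FPKM in OCI wild type to 195 FPKM in OCI knockdown 2. HBE1, an embryonic globin, had 4.34 FPKM in OCI wild type and 112 FPKM in OCI overexpression. GNLY, a granule protein of cytotoxic lymphocytes, had 18.1 FPKM in the library labelled H929 AIMP1 knockdown 1, 7.38 FPKM in H929 knockdown 2 and at most 1.79 FPKM elsewhere. EGR1 had 198 FPKM in H929 knockdown 2 and 7.00 FPKM in H929 protein, and 178 FPKM in OCI protein and 5.77 FPKM in OCI overexpression.

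RN7SL1, RN7SL2, RN7SK, RMRP and RPPH1 made up 49.6% of the FPKM sum in OCI protein, where the RN7SL genes and RN7SK were listed at 0, and 72.2% to 80.7% in the 9 other libraries. Lists of p53 targets, glycolysis and hypoxia, MAPK cascade members, cytokines with chemokines and bone factors, and myeloma translocation genes were called by camera in no comparison, the lowest adjusted p being 0.0627, for cytokines in OCI against H929. Medians, means and tests of uncalled lists differed in sign in some cases, such as MAPK cascade members in protein (median 0.17, mean 0.07, test down). Markers of erythroid, myeloid, stromal and T or NK cells had 1, 2, 4 and 3 tested genes, too few for a list test; their most abundant genes were HBD (at most 18.8 FPKM), CTSS (18.1 FPKM), PDGFRB (6.99 FPKM) and GNLY (18.1 FPKM).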
